A study of Mus musculus with 10 samples.

How the data were processed

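Histone marks were profiled by chromatin immunoprecipitation and sequencing in 10 libraries from 3 mouse embryonic stem (ES) cell lines, 1 library per line, condition and mark. The line XT67E1 was profiled for H3K4me3 and H3K27me3 undifferentiated, after 4 days of all-trans retinoic acid (atRA) and as 10-day embryoid bodies (EBs). The lines LF2 and E14 were profiled for H3K27me3 undifferentiated and as 10-day EBs. As background, XT67E1 and LF2 are female lines and E14 is a male line. The lines do not all share a strain, and an effect of strain was not tested. Per the labels' protocols, chromatin was sheared by sonication and the libraries were read on Illumina Genome Analyzers. Groups were taken from the sample labels.

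The deposited files list read positions, with no value per row: each row is an interval of 200 bp with no strand. The coordinates are those of mm9, the build in the submitters' processing notes. The aligner, the read filters and the extension to 200 bp are not given in the sources used here. No interval occurred more than once within a file. The files of a set held the same number of reads, which was 2252395 in each of the 3 H3K4me3 libraries, 8380007 in each of the 3 XT67E1 H3K27me3 libraries and 4531733 in each of the 4 LF2 and E14 libraries. Total depth therefore did not differ within a comparison, and a stronger or weaker pull-down overall cannot be seen in the totals.

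The midpoint of each interval was counted in bins. No gene annotation of mm9 was used here, so bins replaced genes, as had been planned for this case, and regions are given by mm9 position, counted from 1, without gene names. The bins were 10 kb for H3K27me3 and 2 kb for H3K4me3. The 15 gene lists and the windows around transcription start sites that had been fixed beforehand could not be placed and are not analysed here. Counting repeated positions once would have changed nothing. Counts were scaled to autosomal reads (RPM, reads per 1e6 autosomal reads), and log2 ratios used counts plus a pseudocount of 1 read, which understates the change of bins with few reads. Bins with at least 20 reads in the 2 libraries compared were kept. The minimum of 20 reads kept 13624 X bins in XT67E1 EBs and 3270 in E14 EBs, so read densities over all of X are given beside the bin medians.

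With 1 library per group, a comparison of 2 libraries has no replicate check, and no p-value was computed across bins. The X median was set against the medians of the 19 autosomes and against 10000 random autosomal lists of the same size, matched on read number. Each autosome was also set against 500 such lists of the other autosomes. Bins were called higher or lower by size, at 2-fold or more with an exact conditional binomial 95% interval of the ratio that excludes 1. The number of such calls that counting error alone gives was drawn 20 times per comparison. Intervals, Wilson intervals of read shares included, cover counting error only.

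EBs against undifferentiated cells in H3K27me3 were also tested over the 3 lines with limma 3.58.1 in R 4.3.3, with the cell line as a block, an intensity trend, at least 60 reads over the 6 libraries and a Benjamini-Hochberg adjusted p under 0.05, two-sided. The lines pair the libraries: the deviations from the condition means correlated at 0.19 in XT67E1, 0.09 in LF2 and 0.24 in E14. The p-values rest on the spread between 3 lines with 1 library per condition, moderated by the spread pooled over bins. The test had 40.4 degrees of freedom in total, most of them from this pooling. The SE and p-value of a bin can therefore be smaller than the spread of its own 3 values would give. Chromosomes were tested as lists of bins with limma's camera, with a preset correlation of 0.01 and with an estimated one. Tested on simulated data with 225476 bins and an added variance set at 0.02, not estimated from the libraries, this test recovered 24% of bins raised 2-fold, 100% of those raised 4-fold, 4% of those lowered to 0.5 and 32% of those lowered to 0.25, with 2 false calls. On simulated reads, the size rule recovered from 92.0% (H3K4me3, atRA) to 99.0% (H3K27me3, XT67E1) of 200 bins changed 4-fold either way. A simulated X shift of 0.32 (log2) was read back as 0.29 (LF2) to 0.34 (H3K4me3, atRA).

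The named bins are, per comparison, taken from the 10 highest and 10 lowest log2 ratios among called bins with at least 50 reads (H3K27me3) or 30 reads (H3K4me3) in the 2 libraries, and for limma from the 10 highest and 10 lowest among called bins with the same direction in the 3 lines. Designs, named-bin rules and most alternatives were chosen before the data were examined. The alternatives were no read minimum, a pseudocount of 5 reads, background scaling (reads in autosomal bins with coverage up to the median), median-of-ratios scaling, 10 kb bins for H3K4me3, limma voom, no replicate block and leaving out each line. Bins of 1, 4, 5 and 50 kb, and leaving out chromosomes 8 and 14, were added after seeing the data. So were the matched lists for autosomes, the comparison of called bins with other H3K4me3-marked bins, the profile along X, its division at 109 Mb and the comparison of bins with and without H3K4me3. A 10 kb bin was taken as H3K4me3-marked when it held a 2 kb bin with at least 40 reads over the 3 XT67E1 libraries. X bins with few E14 reads were those with E14 H3K27me3 reads up to the median of X. Background bins of H3K4me3 were defined in 2 ways, the second after the first had given its values: first as the bins with H3K4me3 reads up to the autosomal median, then as the bins that neither are H3K4me3-marked nor adjoin a marked bin. The values from both are given in the closing part. Counting and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.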

Results

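Genome-wide positions of H3K4me3, a mark of active promoters, and of H3K27me3, the mark that Polycomb complexes place on silent chromatin, were compared before and after differentiation of mouse ES cells. The series is about X inactivation, the silencing of 1 X in female cells, which begins when female ES cells differentiate. XT67E1 was the line with both marks and both ways of differentiation, 4 days of atRA and 10 days as EBs. LF2 and E14 were compared as EBs in H3K27me3. Each of the 10 libraries was the single sample of its group, with 2252395 reads for H3K4me3, 8380007 for H3K27me3 in XT67E1 and 4531733 for H3K27me3 in LF2 and E14.

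The share of H3K27me3 reads on X separated the male line from the female lines before differentiation. In undifferentiated cells, X held 4.28% of the reads in XT67E1 (Wilson 95% interval 4.27 to 4.30), 3.70% in LF2 (3.68 to 3.72) and 2.63% in E14 (2.61 to 2.64). Per unit length this was 0.664, 0.570 and 0.400 of the mean autosomal density. X density in XT67E1 was 1.66 times that in E14 and in LF2 1.42 times, while autosomes other than chromosome 8 lay between 0.943 and 1.01 times in XT67E1 and between 0.924 and 1.11 in LF2. Chromosome 8 itself had 1.49 times the mean autosomal density in undifferentiated XT67E1, 1.23 times in LF2 and 0.989 in E14. In EBs the shares on X were 5.10% in XT67E1 (5.08 to 5.11), 4.90% in LF2 (4.88 to 4.92) and 2.44% in E14 (2.43 to 2.45).

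**Figure D1:**
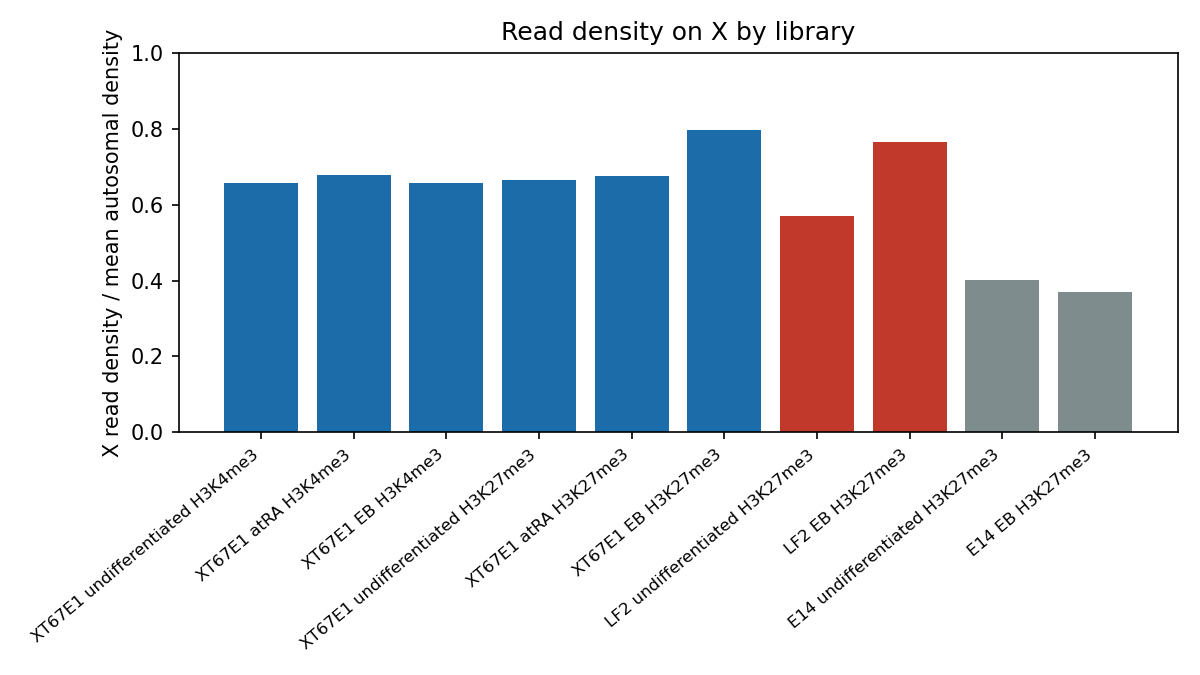
Bars give the read density on X over the mean autosomal density of each library (no unit), coloured by cell line, 1 library per bar. In H3K27me3 the bars of XT67E1 and LF2 are higher in EBs (0.797 and 0.765) than undifferentiated (0.664 and 0.570), and those of E14 are 0.371 and 0.400.

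In XT67E1, H3K27me3 was higher over nearly the whole X in EBs than in undifferentiated cells. X read density was 1.20 times that of undifferentiated cells (95% interval 1.20 to 1.21, counting error), outside the range of the 19 autosomes, which ran from 0.956 to 1.03. The median X bin lay 0.25 (log2) above the autosomal median, the highest autosome being chromosome 11 at 0.07, and above 100% of the random autosomal lists. Of 148 windows of 1 Mb on X, 147 lay above the autosomal median and 51 lay above the upper limit of the central 95% of autosomal windows. The highest value, 0.71, was in the window that starts at 71 Mb. The gain was larger where the line carried H3K4me3: X bins with H3K4me3 had a median log2 ratio of 0.67 against 0.25 in such autosomal bins, and the other X bins 0.26 against 0.01.

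At the 2-fold rule 6025 bins were higher and 1832 lower in XT67E1 EBs, where counting error alone gave means of 1531 and 1423. On X 6.84% of bins were higher, against 2.25% on autosomes. The bins with the highest ratios were on chromosome 5 from 92530001 to 92540000 (73 reads in EBs, 5 undifferentiated, log2 ratio 3.63, counting interval 2.59 to 5.55), on chromosome 4 from 135800001 to 135810000 (104 and 10 reads, 3.27, interval 2.45 to 4.49) and on chromosome 1 from 121310001 to 121320000 (170 and 19 reads, 3.11, interval 2.49 to 3.94). The lowest was on chromosome 9 from 84210001 to 84220000, with 12 and 43 reads (-1.75, interval -2.89 to -0.88). Background scaling moved all bins by -0.11 and gave 3860 higher and 3382 lower bins.

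LF2 showed a larger difference on X that was uneven along the chromosome. X density in EBs was 1.34 times that of undifferentiated cells (1.33 to 1.35), with autosomes from 0.916 to 1.13, and the X median lay 0.46 above the autosomal median, against 0.19 for chromosome 8, the highest autosome. Against lists matched on read number, X lay 0.40 higher and chromosome 8 0.27 higher. The ratio was divided at 109 Mb, the point that best separated its own 1 Mb windows along X. From the start of X to 109 Mb, density in EBs exceeded that of undifferentiated cells by 0.59 (log2, interval 0.57 to 0.60). Beyond 109 Mb it was 0.994 times (log2 -0.01, interval -0.03 to 0.01), a mean of higher and lower windows, such as 0.29 in the window at 111 Mb and -0.34 in that at 131 Mb. In X bins with few H3K27me3 reads in E14, the same parts of X gave 0.77 (0.75 to 0.79) and 0.16 (0.13 to 0.19), scaled to all autosomal reads. Autosomal bins chosen in the same way also held more reads in EBs, such as 94969 undifferentiated and 106570 in EBs on chromosome 1. The 0.16 therefore cannot be read as a gain over such autosomal bins. Relative to them, the density of all of X was 0.588 undifferentiated and 0.779 in EBs. In XT67E1 the same parts of X, over all bins, gave 1.21 and 1.18 times, and in E14 0.923 and 0.934 times. Before 109 Mb the X bins with H3K4me3 in XT67E1 had an LF2 median of 0.93, against -0.11 in such autosomal bins and 0.65 in the other X bins of that part. Beyond it, they had a median of -0.32.

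In LF2 EBs 8956 bins were higher and 4573 lower by the 2-fold rule, where counting alone gave 2406 and 2309. On X 19.4% of bins were higher, against 4.01% on autosomes. The highest ratios were on chromosome 7 from 152040001 to 152050000 (79 reads in EBs, 7 undifferentiated, log2 ratio 3.34, interval 2.40 to 4.88) and on X from 55280001 to 55290000 (68 and 8 reads, 2.95, interval 2.05 to 4.37). The lowest was on chromosome 2 from 11420001 to 11430000 (12 and 83 reads, -2.67, interval -3.78 to -1.89). The balance of calls depended on the scaling: background scaling, which moved all bins by -0.23, gave 3989 higher and 10773 lower bins, and median scaling 6569 and 6456.

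In the male line E14, X did not gain H3K27me3. X density in EBs was 0.927 times that of undifferentiated cells (0.919 to 0.935), below the range of the autosomes, 0.965 to 1.08, and 0 of 148 X windows lay above the upper limit of the central 95% of autosomal windows. The median over the 3270 X bins with enough reads was near that of the autosomes in 10 kb bins, with medians of -0.0027 for both. Bins with equal counts in both libraries take about this value, and the counting interval of the difference was -0.07 to 0.07. Against autosomal lists matched on read number the X median was higher by 0.09, above 98.5% of them, while the highest autosome lay 0.08 above its own matched lists. The X shift depended on bin size, at -0.17 in 5 kb bins and -0.063 in 50 kb bins. The 2-fold rule gave 4138 higher and 5963 lower bins, where counting gave 2354 and 2608, and background scaling, which moved all bins by 0.11, gave 6560 and 3888. Large single-bin ratios occurred in this line as well: the highest were on X from 55280001 to 55290000 (91 reads in EBs, 6 undifferentiated, log2 ratio 3.71, interval 2.74 to 5.40) and on chromosome 17 from 35640001 to 35650000 (89 and 6 reads, 3.68, interval 2.71 to 5.37). The lowest was on chromosome 17 from 46160001 to 46170000 (20 and 155 reads, -2.90, interval -3.71 to -2.28).

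The X shift in XT67E1 EBs exceeded that in E14 EBs by 0.25 (log2), with a range of -0.04 to 0.05 for the same difference over the 19 autosomes. In 5 kb bins, where the E14 shift was -0.17, it was 0.42, and in 50 kb bins 0.31. LF2 exceeded E14 by 0.46 (autosomes -0.11 to 0.19), or by 0.65 in 5 kb bins. The excess of LF2 over XT67E1, 0.21, lay within the range of the autosomes, -0.11 to 0.21. Over the 3 lines the mean log2 density ratio of X was 0.19 ± 0.27 (SD, n = 3), with an exact two-sided sign-flip p of 0.5, and 0.25 is the smallest p that 3 lines allow.

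**Figure D2:**
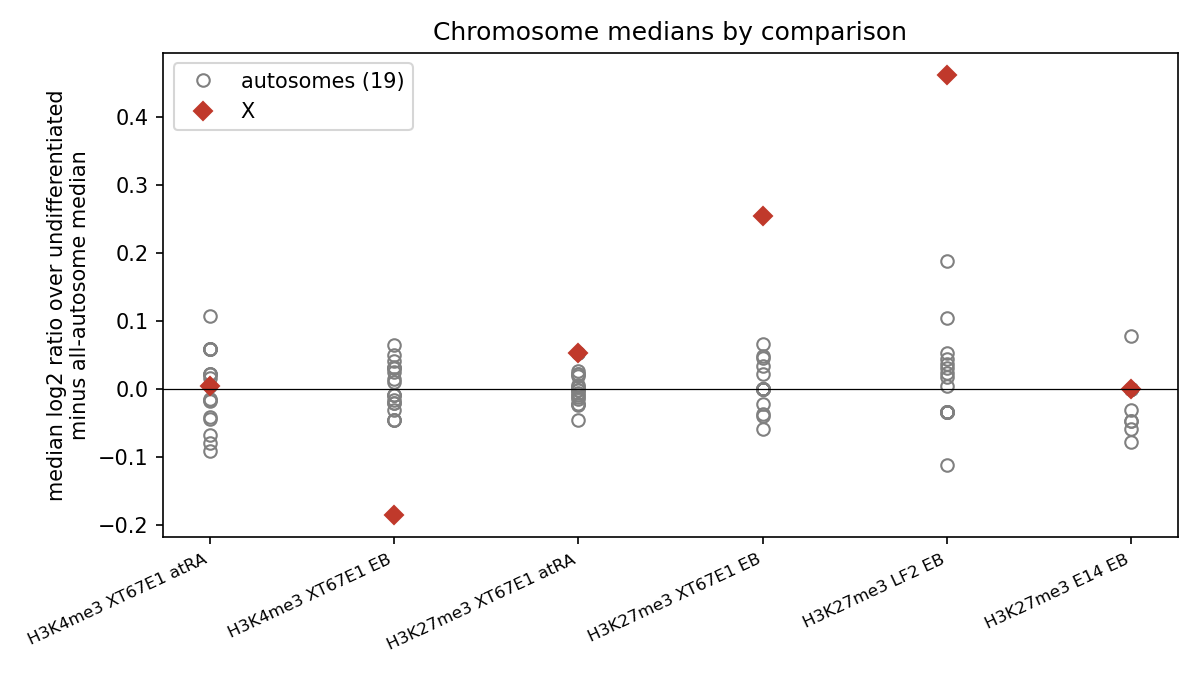
Each grey circle is the median log2 ratio of an autosome and each red diamond that of X, minus the median over all autosomal bins, for the 6 comparisons with undifferentiated cells. X lies above the autosomes for H3K27me3 in EBs of XT67E1 (0.25) and LF2 (0.46) and below them for H3K4me3 in EBs of XT67E1 (-0.19).

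**Figure D3:**
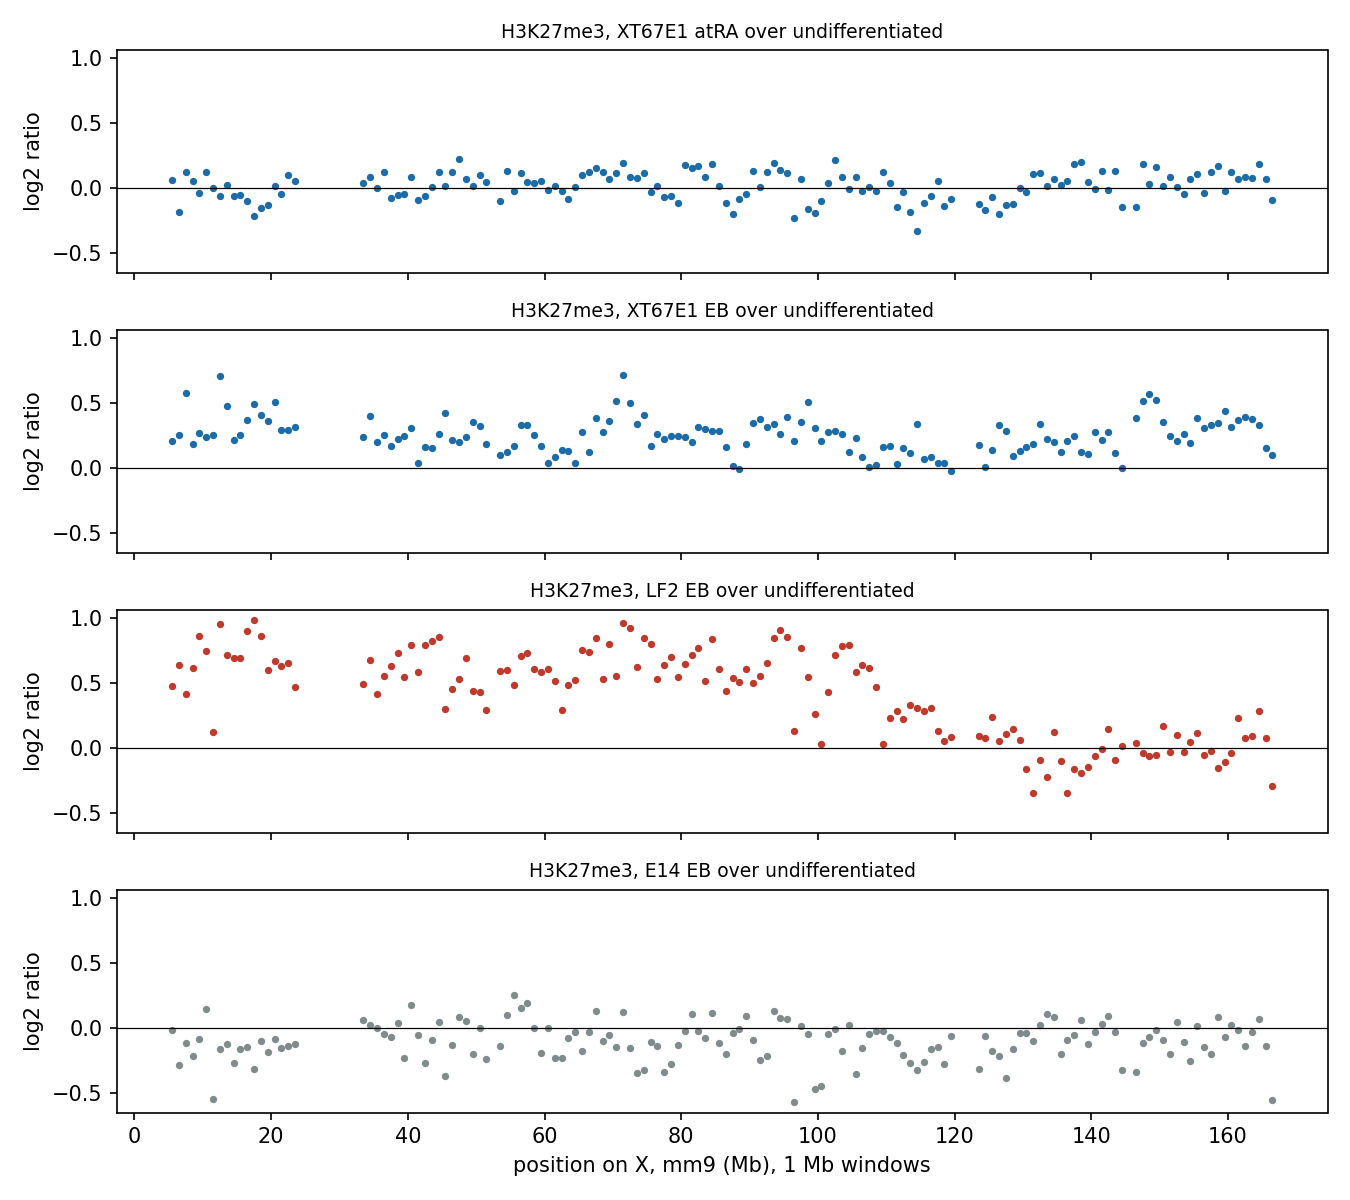
Points are log2 ratios of H3K27me3 reads per autosomal read total in 1 Mb windows along X (mm9, Mb), treated over undifferentiated, 1 panel per comparison. Values in XT67E1 EBs lie above 0 in most windows, with a maximum of 0.71. Values in LF2 EBs are high up to about 109 Mb and lower beyond it, still above 0 in the windows next to that point and around 0 further on.

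Single regions gained or lost H3K27me3 in EBs over the 3 lines. Tested with limma and the cell line as a block, 275 of 227429 bins changed at an adjusted p under 0.05, of which 194 rose and 81 fell. The balance of rises and falls depended on XT67E1: 200 bins rose and 216 fell without that line. It was 254 and 70 without LF2 and 439 and 177 without E14 (416, 324 and 616 bins in all). In the simulated data the test recovered 24% of bins raised 2-fold but 4% of those lowered to 0.5. More rises than falls among the calls therefore cannot be read as more gains than losses of the mark. Each called bin had the same direction in 3 of 3 lines, which the call itself nearly requires, and the sizes differed between lines, as on chromosome 19 from 53380001 (-0.37, -1.76 and -2.41 in XT67E1, LF2 and E14). The bin on X from 55280001 to 55290000 rose by 2.87 (log2, SE 0.28, adjusted p = 3.8e-08), with 1.94 in XT67E1, 2.95 in LF2 and 3.71 in E14. Chromosome 7 from 152040001 to 152050000 rose by 2.77 (SE 0.24, adjusted p = 5.5e-09) and chromosome 4 from 135800001 to 135810000 by 2.72 (SE 0.24, adjusted p = 5.5e-09). Further rises of at least 2.29 were on chromosome 17 from 35640001 to 35650000 (2.52, SE 0.31), chromosome 4 from 129050001 to 129060000 (2.39, SE 0.26) and chromosome 7 from 28110001 to 28120000 (2.29, SE 0.24). The largest falls were on chromosome 19 from 30100001 to 30110000 (-1.87, SE 0.25, adjusted p = 6.1e-05), chromosome 18 from 83080001 to 83090000 (-1.86, SE 0.26, adjusted p = 9.2e-05) and chromosome 2 from 11420001 to 11430000 (-1.68, SE 0.26, adjusted p = 0.00076).

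The called bins tended to differ in the opposite direction in H3K4me3, which came from separate XT67E1 libraries, although most did not reach 2-fold. Of the 194 bins that rose in H3K27me3, 175 had enough H3K4me3 reads, and their median H3K4me3 log2 ratio in EBs was -0.86 (quartiles -1.30 and -0.34). H3K4me3 was at least 2-fold lower in 69 of them and at least 2-fold higher in 1, that is 39.4% lower against 4.55% over all bins. After 4 days of atRA their median H3K4me3 ratio was -0.94, over 171 bins. Of the 81 bins that fell, 63 had enough reads, with a median of 0.53 in EBs, and 14 were at least 2-fold higher and 0 at least 2-fold lower. H3K4me3-marked bins were lower in EBs in general, with a median of -0.25 over 9998 marked bins that were not called, of which 6.32% were at least 2-fold lower and 1.79% higher. The 100 marked bins among those that rose had a median of -1.07, with 53 at least 2-fold lower, and the 35 among those that fell had a median of 0.70, with 11 at least 2-fold higher. The bin on chromosome 7 from 152040001 held 230 H3K4me3 reads undifferentiated and 59 in EBs, that on chromosome 17 from 35640001 held 304 and 103, and that on X from 55280001 held 333 and 101. The bin that fell on chromosome 18 from 83080001 held 27 and 82.

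On X, 18 of the bins rose and 1 fell. As a list, the 11142 X bins had a mean log2 change of 0.22, and the camera adjusted p over 20 chromosomes was 2.6e-05 with the preset correlation. With an estimated correlation it was not called (adjusted p = 0.98), and no other chromosome was called with the preset correlation. Without XT67E1 the X mean was 0.11 (adjusted p = 0.41) and without LF2 it was 0.10 (adjusted p = 0.16). Without the block 10 bins were called, all of them rises, and with limma voom 576.

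**Figure D4:**
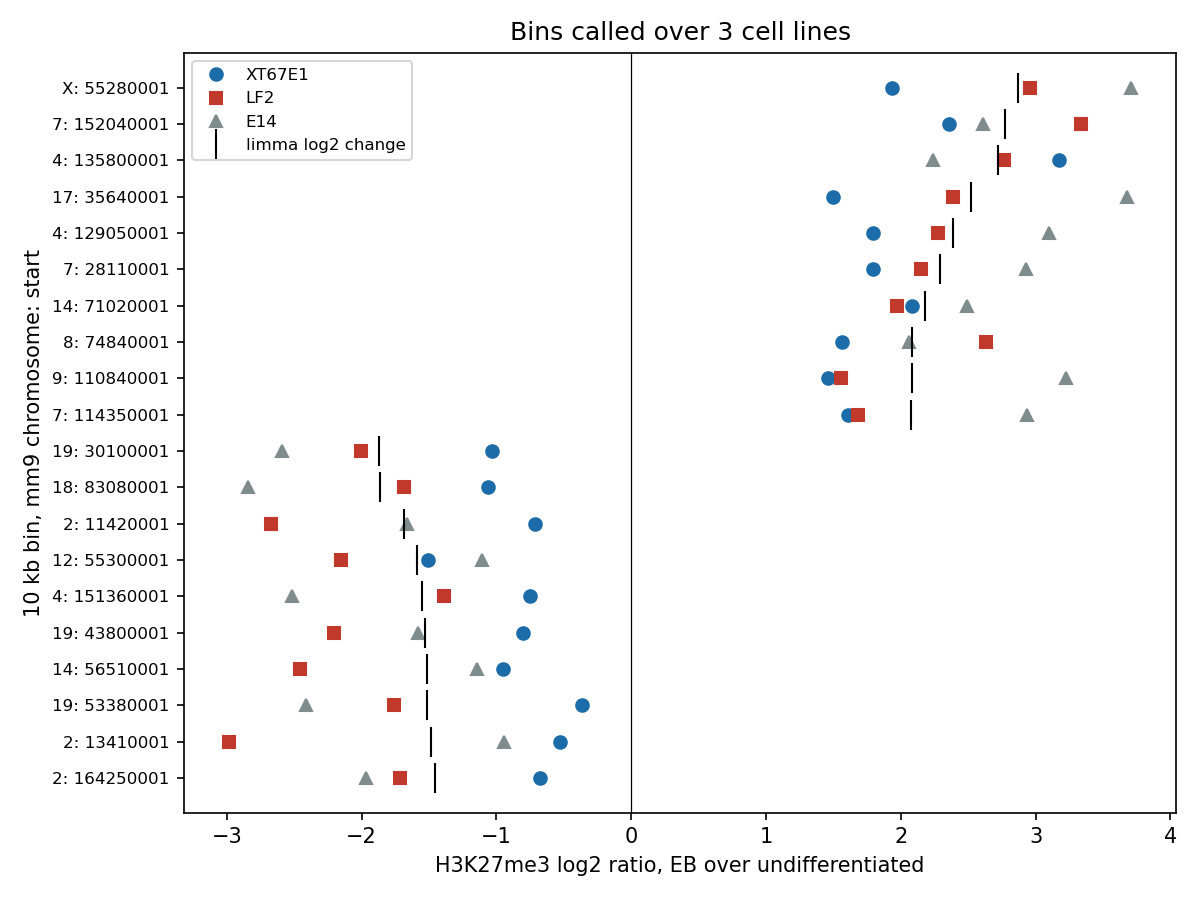
H3K27me3 log2 ratios, EBs over undifferentiated, of the 10 bins with the largest rise and the 10 with the largest fall in the test over 3 lines (rows are mm9 chromosome and bin start). Symbols are single lines and the black ticks the fitted change. The bin on X at 55280001 is at 1.94, 2.95 and 3.71 in XT67E1, LF2 and E14.

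After 4 days of atRA, X in XT67E1 barely differed from the autosomes in H3K27me3. X density was 1.02 times that of undifferentiated cells (1.01 to 1.02), within the autosomes' range of 0.953 to 1.06. The X median lay 0.05 above that of the autosomes, no higher than chromosome 17 (0.05), although it exceeded autosomal lists matched on read number by 0.09, above 100% of them, with the highest autosome at 0.06 over its own. Of the X windows 0 of 148 windows lay above the upper limit of the central 95% of autosomal windows. Single regions did differ by 2-fold or more, with 2080 bins higher and 4881 lower against 1701 and 1413 from counting alone. Background scaling, which moved all bins by 0.14, gave 3915 higher and 2880 lower. The highest ratios were on chromosome 1 from 121310001 to 121320000 (270 reads with atRA, 19 undifferentiated, log2 ratio 3.76, interval 3.16 to 4.58) and chromosome 7 from 152040001 to 152050000 (117 and 15 reads, 2.88, interval 2.18 to 3.85). Among the lowest were chromosome 2 from 17960001 to 17970000 (19 and 93 reads, -2.23, interval -3.09 to -1.57) and X from 6890001 to 6900000 (2.99 and 13.1 RPM, -2.08, interval -2.83 to -1.48).

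H3K4me3 on X in XT67E1 was lower in EBs at the regions that carried the mark. The median over 519 X bins of 2 kb lay 0.19 below the autosomal median (log2 -0.19, counting interval -0.25 to -0.12), below the lowest autosome (-0.05) and below 100% of the random lists. The shift was absent with no read minimum (-3.9e-06), where bins with few reads enter, and was -0.13 in 10 kb bins. Of these X bins 17.1% were at least 2-fold lower and 1.16% higher, against 12.8% and 2.88% on autosomes. X density over all H3K4me3 reads did not differ, at 1.00 times that of undifferentiated cells (0.991 to 1.01). In all, 444 bins were higher and 2044 lower, where counting gave 134 and 124. The median over autosomal bins was itself -0.33, and scaling it away gave 1043 higher and 1109 lower bins. Away from H3K4me3-rich bins, reads rose in EBs, from 70837 to 76809 on X and from 111104 to 121915 on chromosome 1. A weaker pull-down in the EB library could lower marked bins on X and autosomes by unlike amounts. Whether it gave part of the X shift was not tested. The lowest bin was on chromosome 2 from 151848001 to 151850000, with 0 reads in EBs and 35 undifferentiated. The highest were on chromosome 13 from 29042001 to 29044000 (34 and 2 reads, log2 ratio 3.54, interval 2.12 to 7.19), chromosome 18 from 53624001 to 53626000 (33 and 2 reads, 3.50, interval 2.08 to 7.15) and chromosome 1 from 170360001 to 170362000 (33 and 3 reads, 3.09, interval 1.79 to 5.81).

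After atRA the H3K4me3 median on X did not part from that of the autosomes (log2 difference 0.00, counting interval -0.06 to 0.07), and X density was 1.03 times that of undifferentiated cells (1.02 to 1.04), within the autosomes' range of 0.950 to 1.04. By size 742 bins were higher and 1870 lower, where counting gave 131 and 112. The gains were on chromosome 2 from 147870001 to 147872000 (30 reads with atRA, 0 undifferentiated), chromosome 18 from 11054001 to 11056000 (35 and 1 reads) and chromosome 8 from 28088001 to 28090000 (67 and 3 reads, log2 ratio 4.09, interval 2.87 to 6.80), among others. The same 2 kb bin on chromosome 13 from 29042001 held 40 reads with atRA and 2 undifferentiated. Chromosome 4 from 130176001 to 130178000 held 0 reads with atRA and 34 undifferentiated, and chromosome 1 from 193752001 to 193754000 held 1 and 54 (-4.78, interval -11.1 to -3.21).

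Across bins the marks tended to differ in opposite directions in XT67E1. In EBs Spearman's rho between the H3K4me3 ratio of a 2 kb bin and the H3K27me3 ratio of the 10 kb around it was -0.30 over 15182 autosomal bins and -0.18 over 518 X bins (Pearson's r -0.33 and -0.20). After atRA rho was -0.19 and -0.12. These are relations across bins of the same libraries, and bins are not independent replicates. On autosomes the median H3K27me3 ratio in EBs was 0.52 where H3K4me3 was at least 2-fold lower, 0.25 where it was within 2-fold and -0.13 where it was at least 2-fold higher. On X it was positive in each class, at 0.75, 0.67 and 0.43, the last over 14 bins.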

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

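The tests below were all chosen after the results were seen. The X read density ratio in H3K27me3, EBs over undifferentiated, went opposite ways in the cell lines: 1.20 in XT67E1 and 1.34 in LF2 against 0.927 in E14. With 1 library per group this difference was not tested. Chromosome Y, which no comparison used, held 912 reads in undifferentiated E14 and 674 in E14 EBs, against 98 to 124 in the H3K27me3 libraries of the other lines.

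In XT67E1 EBs, H3K27me3 on X was higher by 0.25 (log2) over the autosomes. More X copies in the EB culture would raise background reads of both marks, and X density in bins with few E14 reads was indeed 0.682 undifferentiated and 0.799 in EBs in H3K27me3, which a spread of the mark would also give, yet away from H3K4me3-rich bins the X ratio in H3K4me3 was 1.00 (0.991 to 1.01), or 0.987 (0.975 to 0.999) with the bins defined first, which argues against this only if both marks came from the same cultures, which is not known. A uniform copy-number change within the H3K27me3 libraries would act alike on all bins, but X exceeded autosomes by 0.17 more in bins with H3K4me3 (interval 0.11 to 0.23, autosomes -0.07 to 0.07), so it cannot be the whole cause, though a part stays open. A stronger pull-down would move matched autosomal bins as well, and X exceeded these by 0.21, with the highest autosome 0.07 above its own matched bins, but this measure was also passed after atRA (0.09 against 0.06) and in E14 EBs (0.09 against 0.08), where X density did not exceed the autosomes, so it leaves a pull-down difference open. The gain may be H3K27me3 placed on the inactive X, with which the lower X ratio in the male line goes, but copy number, pull-down and other differences between the lines, with 1 male line and no replicates, stay open.

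In LF2 EBs X gained H3K27me3 up to 109 Mb but on average not beyond it (0.994 times undifferentiated cells). Beyond it, X minus autosome was -0.21 (log2, interval -0.38 to -0.04) in bins with H3K4me3 and -0.13 in the others. The gain was thus lower on average beyond about 109 Mb. That point was chosen from this same ratio, and windows next to it were still above 0, so these values do not locate an end. A higher X copy number before 109 Mb, acting alike on all bins there, cannot be the whole cause by itself. X exceeded autosomes there by 0.45 more in bins with H3K4me3 in XT67E1 (interval 0.34 to 0.57, autosomes -0.14 to 0.10). LF2 had no H3K4me3 library. Its autosomal bins also parted by this mark, with medians of -0.11 with it and 0.07 in the others. A pull-down difference was not tested in LF2, so copy number together with such a difference stays open. Part of the step may still be copy number. If LF2 carried distal X in 1 copy, its undifferentiated density there would match E14. Beyond 109 Mb it was 1.27 times E14 (log2 0.34, interval 0.32 to 0.36), against 1.67 times in XT67E1. The LF2 value is a mean of unlike parts, since from 110 to 130 Mb the log2 ratio was 0.09, near the value of 1 copy. The rest of X had 0.51, but this includes X before 109 Mb. A single copy of part of distal X, a weaker spread of the mark there, or both, therefore stay open.

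Chromosome 8 had 1.43 to 1.52 times the mean autosomal density in the 6 XT67E1 libraries of both marks. In bins with E14 H3K27me3 reads up to each chromosome's median, its H3K27me3 density in XT67E1 was 1.53 undifferentiated, 1.56 after atRA and 1.51 in EBs. These values were not part of the test below, and they go with an extra copy. An extra copy of this chromosome would also raise its density in H3K4me3 background bins, and the answer depended on how these were defined. The definition tried first, bins with few H3K4me3 reads, gave 1.00 to 1.03 in the 3 H3K4me3 libraries; after this was seen it was replaced by bins away from H3K4me3-rich ones, which gave 1.42 in each. The first picks bins by low counts in the libraries it measures and kept 20.2% of chromosome 8 bins against 52.8% on other autosomes. Such picking brings the kept bins of a denser chromosome near the mean, so its 1.00 to 1.03 cannot count against an extra copy. The second kept 87.5% and 89.4%, which is why it was preferred. Because that choice followed the outcome, an extra copy stays a candidate explanation that these tests leave open, and no biological explanation was tested.

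For the test over 3 lines, the real split of the 6 libraries gave 275 bins and the highest of the other splits gave 0, so 1 of 10 splits gave as many. Of the other splits, 3 also parted every line's pair, and 6 parted 1 pair. With 10 splits, the share cannot go under 0.05.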

How the results depend on the processing

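Of 118 values recomputed under an alternative, 71 kept to the main value by the rule for their kind, 45 moved, 2 lost their call and 0 reversed. Counts of bins have no sign, so the 0 says nothing of them. Under background scaling the balance of higher and lower H3K27me3 bins turned in LF2 EBs, from 8956 and 4573 to 3989 and 10773. It also turned in E14 EBs, from 4138 and 5963 to 6560 and 3888, and after atRA, from 2080 and 4881 to 3915 and 2880. In XT67E1 EBs it kept its direction, at 3860 and 3382. X minus autosome stayed positive in H3K27me3 EBs of XT67E1 and LF2 under each alternative run. The cause of each move was not tested unless given. Bins of 1, 4, 5 and 50 kb, the 2 definitions of background bins, the comparison with H3K4me3-marked bins and leaving out chromosomes 8 and 14 were chosen after seeing the data. Windows around start sites and the fixed gene lists were not run, and counting positions once has no effect.

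X minus autosome (log2), H3K27me3: in XT67E1 EBs 0.22 with a pseudocount of 5 and 0.24 in 50 kb bins. In LF2 EBs it was 0.36 with no minimum, 0.36 with a pseudocount of 5, 0.48 in 5 kb bins, 0.38 in 50 kb bins and 0.49 without chromosomes 8 and 14. In E14 EBs it was -0.17 in 5 kb bins, and after atRA it was 0.046, 0.018 and 0.055 with a pseudocount of 5, 5 kb and 50 kb bins. For H3K4me3 it was 0.078 in 4 kb bins after atRA, and -3.9e-06 in EBs with no minimum, where most bins hold few reads. XT67E1 minus E14 was 0.42 and 0.31 in 5 and 50 kb bins, and LF2 minus E14 0.65 in 5 kb bins.

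Bins 2-fold higher and lower: with no minimum 2849 and 4772 (H3K4me3 atRA) and 3014 and 4263 (H3K4me3 EBs). Median scaling gave 1043 and 1109 in the latter. With a pseudocount of 5, H3K27me3 gave 1126 and 2252 (XT67E1 atRA), 3159 and 745 (XT67E1 EBs), 5603 and 2544 (LF2) and 2090 and 3647 (E14). With background scaling it gave 3915 and 2880, 3860 and 3382, 3989 and 10773, and 6560 and 3888.

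Limma, 275 bins: 10 with no replicate block, 167 with background scaling, 576 with voom, 102 with no minimum and 559 in 50 kb bins. Leaving out a line gave 324 to 616. The 194 rises and 81 falls became 200 and 216 without XT67E1, 254 and 70 without LF2 and 439 and 177 without E14. The X list's mean (0.22) was 0.10 to 0.37 without a line, and was no longer called without XT67E1 (0.11) or LF2 (0.10). Adjusted p of the X list with an estimated correlation ran from 0.64 to 0.99, so it was not called in any of these fits. Its adjusted p with the preset correlation ran from 1.0e-14 (without E14) to 0.41 (without XT67E1). In the simulated data limma recovered 32% of bins lowered to 0.25 and 100% of those raised 4-fold, at 1 depth, so the effect of depth was not tested.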

Other observations

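The tests in this part were chosen after the data were seen. Step-like changes of density also occurred on autosomes of LF2. Against E14 in EBs, the mean log2 ratio on chromosome 8 was 0.16 up to 80 Mb and 0.76 beyond it, and on chromosome 14 it was -0.04 from 8 to 66 Mb and 0.56 outside that part. In undifferentiated cells the steps lay at 80 Mb (0.10 and 0.43) and 54 Mb (-0.22 and 0.29). Within LF2, EBs over undifferentiated cells, chromosome 8 was at 0.49 from 81 to 107 Mb and at 0.08 outside it, a step of 0.41 against the 0.59 found on X. No other autosome had a step of over 0.4 in LF2 EBs against E14. XT67E1 over E14 also had a step on chromosome 14. From 93 to 103 Mb its log2 ratio was 0.46 in undifferentiated cells and 0.39 in EBs, against -0.04 and -0.0003 outside that part. A ratio to E14 therefore does not tell which line differs there.

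Over 11142 X bins with enough reads in the 3 lines, 2652 were higher in EBs in each line and 533 lower in each. On autosomes these numbers were 32036 and 28033 of 216287 bins.

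Over 148 windows of X, the H3K27me3 ratios in EBs correlated at r = 0.21 between XT67E1 and LF2, at 0.18 between LF2 and the male line E14 and at 0.057 between XT67E1 and E14. Over 2390 autosomal windows these pairs gave -0.02, 0.03 and 0.18. H3K4me3 and H3K27me3 ratios of XT67E1 EBs correlated at r = -0.54 over the same windows and at -0.49 over the autosomal windows. H3K4me3 in XT67E1 EBs correlated with H3K27me3 in LF2 EBs at 0.40 over autosomal windows and at 0.038 over X, and with H3K27me3 in E14 EBs at -0.17 and -0.0078. These are correlations across windows, which are not independent replicates.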
